A study of Mus musculus with 36 samples.

How the data were processed

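RNA was measured by sequencing of total RNA from 36 libraries of mouse C57BL/6 pro-T cells. Per the labels, cells were grown with DL4, SCF and IL7, left unstimulated for 18 h and then stimulated for 8 h, and RNA was extracted with a Maxwell 16 LEV kit. The labels state this protocol for the series as a whole. The cytokine experiment held 24 libraries in 8 groups of 3, and the transduction experiment 12 libraries in 4 groups of 3. Cells of the latter were Dll4-Cas9 pro-T cells with an empty MSCV-GFP vector, a Pten gRNA-GFP vector, the Pten gRNA vector and a TAL1-mCherry vector, or both of these with SCF.

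The deposited files hold raw read counts per gene, which the authors made, per the labels, with FastQC, TopHat2 and HTSeq on build mm10, with no versions or settings stated. The values were checked to be whole numbers whose totals differ between libraries, so no normalization was undone. The stimulated files list 24062 gene symbols and the transduced files 46078 Ensembl identifiers, of which 45143 were matched to a symbol, while 112 that share a symbol were kept under their identifier. HTSeq summary lines were left out of the gene counts and used for the share of reads outside genes (no-feature share), which was 25.9 to 46.7% of assigned, ambiguous and no-feature reads in the stimulated libraries and 13.5 to 25.3% in the transduced ones. Reads assigned to genes had a median of 11.2 and a highest value of 30.1 in units of 1e6 per stimulated library, and a median of 23.1 per transduced library. The fitted spread between replicates was a common coefficient of variation of 11.8% in the stimulated and 4.1% in the transduced libraries.

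Genes were filtered with filterByExpr by group (12411 stimulated and 14909 transduced genes left, and 12403 matched by symbol for the contrast across experiments), scaled by TMM and tested with the edgeR 4.0.16 quasi-likelihood F-test in R 4.3.3, all libraries of an experiment in 1 fit of group means. Benjamini-Hochberg adjustment ran over all genes tested, and genes passed at an adjusted p under 0.05. Standard errors are the absolute log2 fold change over the square root of F. There were 16 comparisons: 7 stimulations against unstimulated, 3 interactions of stimulus pairs, 5 comparisons of transduced groups, and the difference of the SCF response between experiments. Gene lists (22, of which those with under 5 tested members are given by values only) were tested with edgeR camera at a preset correlation of 0.01, two-sided, adjusted over the lists of a comparison. A member with no reads in a compared group was put at its bound against a floor of 3 counts over the group where a median is given at bounds. Some genes stand on more than 1 list, so results of different lists are not independent. The lists are NOTCH, IL7 and STAT5, E protein, FOXO, ATF4 and p53 target genes, ERK and KIT feedback, TAL1 and GATA complex, early T lineage, S phase, G2 and M phase, ribosome biogenesis and MYC, glycolysis, cholesterol synthesis, apoptosis regulator and interferon response genes, and myeloid, B lineage, NK and innate lymphoid, mast cell and basophil, erythroid and megakaryocyte, and fibroblast stroma marker genes.

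The comparisons, tests, gene lists, the alternatives of the planned kind and the rule for named genes were chosen before the data were examined. Candidates for the largest changes passed the comparison and had a mean count of at least 50 over the libraries compared. Outside the interactions and the difference between experiments, they also showed no overlap between the libraries of the compared groups. From these came the 6 largest rises and falls of the main comparisons and the 4 largest of the others. Up to 4 called members of each list with the smallest p were named without the count and overlap conditions. Pten, Tal1, Kit, Il7r and Notch1 were named throughout, also without these conditions. Members of a list that did not pass are given with their values. Genes with 3 or fewer reads in a compared group are not given by a fold change. Overlaps between responses count genes called in both against the number expected from independent calls.

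Alternatives were DESeq2 size factors, no filter, a stricter filter (CPM of at least 1 in 3 libraries), the replicate number as a block, the DESeq2 1.42.0 Wald test, only the compared groups in the fit, an absolute log2 fold change of at least 1, leaving out each library, and for lists an estimated correlation and fry (limma 3.58.1). The no-feature share as a covariate and exchanged SCF and IL7 labels were added after the data were seen. The fit was tested on simulated data with 2-fold and 4-fold changes: 89.9 and 100% of changed genes were recovered at the size of the DL4 comparison, with 6.44% unchanged genes among the calls, and 94.9 and 100% at the size of the Pten gRNA comparison, with 5.83%. Simulated counts were drawn independently for each gene, with 200 genes changed. These shares need not hold for the real libraries, where genes vary together and more genes were called. Figures were drawn with matplotlib 3.10.9, and files were read with Python 3.11.15 and numpy 2.4.6. Editing at Pten and vector transcripts were left out, since gene counts do not show them.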

Results

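The 36 libraries came from 2 experiments on mouse pro-T cells, which are early T lineage cells grown with the NOTCH ligand DL4, stem cell factor (SCF, the ligand of KIT) and interleukin 7 (IL7). In the stimulated experiment, 24 libraries held 8 groups of 3: cells left for 18 h without stimuli, and cells given DL4, SCF or IL7 for 8 h, alone, in pairs or all at once. The transduced experiment held 4 groups of 3 libraries of Dll4-Cas9 pro-T cells. They had an empty GFP vector, a Pten guide RNA (gRNA), the Pten gRNA and TAL1, or the Pten gRNA, TAL1 and an SCF stimulation. The labels do not say whether replicates were separate cultures. If they were not, p-values measure the spread between libraries and not between cultures. Between replicates of a group, the spread over that of counting alone (chi-square per degree of freedom) was 1.92 to 98.15 in the stimulated libraries. It was 1.48 to 13.84 in the transduced ones. Reads assigned to genes ranged from 6771226 to 30111921 per stimulated library and from 20918960 to 27034422 per transduced library. Levels are read counts scaled by library size (CPM, mean ± SD, n = 3 libraries per group). The log2 fold changes carry the standard error of the edgeR quasi-likelihood fit. On mouse build mm10, the manipulated and receptor genes were Pten on chromosome 19 (32757497 to 32826160), Tal1 on chromosome 4 (115056426 to 115071755), Kit on chromosome 5 (75574916 to 75656722), Il7r on chromosome 15 (9505788 to 9530176) and Notch1 on chromosome 2 (26457903 to 26516663).

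DL4 alone raised genes known as NOTCH targets. Dtx1, which encodes an E3 ubiquitin ligase of the NOTCH pathway (mm10 chromosome 5, 120680202 to 120711927), went from 1.55 ± 0.0977 to 188 ± 30.1 CPM. Il2ra, the interleukin 2 receptor alpha chain gene of early T cells, went from 194 ± 15.2 to 2741 ± 276 CPM. The repressor gene Hey1 rose by 4.92 ± 0.47 on the log2 scale, Myc by 3.00 ± 0.14, Deptor, whose protein binds mTOR, by 3.82 ± 0.27, Notch3 by 2.37 ± 0.18 and Notch1 itself by 1.82 ± 0.15. Il7r rose by 0.74 ± 0.08, and Sell, a homing receptor gene, by 1.12 ± 0.13. Falls were smaller: Flt3, a receptor of uncommitted progenitors, changed by -1.94 ± 0.28, the secreted protein gene Wfdc18 by -2.40 ± 0.44 and Pten by -0.35 ± 0.09. Kit (0.18 ± 0.09, adjusted p = 0.18 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment) and Tal1 (-0.13 ± 0.13) did not pass. Of 18 NOTCH target genes tested, 11 rose and 1 fell (11 and 2 adjusted over the list alone), with a median of 1.78, also with the gene at 0 counts in a group at its bound (camera adjusted p = 3.7e-26). Ribosome biogenesis and MYC genes rose in 20 of 25 (24 adjusted over the list alone), with a median of 0.69. E protein target genes, which include the recombinase gene Rag2 (0.89 ± 0.10), rose in 12 of 22 and fell in 1 (13 and 2 adjusted over the list alone). This list shares Notch1, Notch3, Hes1 and Ptcra with the NOTCH list, so the results of these lists are not independent. Among interferon response genes, 6 of 20 rose and 1 fell (8 and 1 adjusted over the list alone), and the camera call was lost, at adjusted p = 0.11 with an estimated correlation. The edgeR quasi-likelihood F-test with Benjamini-Hochberg adjustment called 1388 of 12411 genes, 785 higher and 603 lower, where Dtx1 had adjusted p = 1.15e-07. Single libraries moved that count: it was 859 without DL4 replicate 2, 739 without DL4 replicate 3, 902 without unstimulated replicate 1 and 784 without unstimulated replicate 2. Pten no longer passed without DL4 replicate 2 or DL4 replicate 3. Tal1 passed (-0.33) with the no-feature share of each library (reads outside genes) as a covariate, chosen after the values were seen.

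In the libraries labelled SCF, genes known as targets of IL7 and STAT5 rose. Cish, the feedback inhibitor of STAT5 signalling (mm10 chromosome 9, 107296026 to 107302784), went from 6.26 ± 0.774 to 65.3 ± 3.71 CPM. The survival gene Bcl2 went from 316 ± 7.25 to 997 ± 83.4 CPM, and Il7r from 296 ± 4.33 to 63.5 ± 0.381 CPM. The kinase gene Pim2 rose by 2.19 ± 0.16, the cyclin gene Ccnd2 by 1.85 ± 0.11, and Lrrc32, whose protein holds latent TGF-beta on the cell surface, by 6.65 ± 0.33. Etv5, an ETS factor gene downstream of ERK, changed by -2.85 ± 0.52, with only 9 reads over all libraries labelled SCF. The AP-1 gene Jun changed by -1.44 ± 0.16, and Dusp6, an ERK phosphatase gene, stood at 2.31 ± 0.595 CPM against 2.28 ± 0.217 unstimulated. Kit fell by 0.57 ± 0.09, while Notch1 (-0.26 ± 0.14), Pten (-0.16 ± 0.09) and Tal1 (0.04 ± 0.13) did not pass. Of 20 IL7 and STAT5 target genes, 14 rose and 3 fell (14 and 3 adjusted over the list alone), with a median of 1.41 (camera adjusted p = 9.8e-23). All 25 ribosome biogenesis and MYC genes rose (25 adjusted over the list alone; median 1.14), with Rrp12 at 1.71 ± 0.11. ATF4 target genes of amino acid supply rose in 19 of 23 and fell in 1 (19 and 1 adjusted over the list alone), led by the asparagine synthetase gene Asns at 3.91 ± 0.31. Cholesterol synthesis genes rose in 19 of 22 (20 adjusted over the list alone; median 1.03), with Hmgcr, the rate-limiting enzyme gene, at 1.15 ± 0.07. ERK and KIT feedback genes rose in 4 of 21 and fell in 2 (4 and 2 adjusted over the list alone), with a median of 0.09, and their camera call was lost, at adjusted p = 0.31 with an estimated correlation. By edgeR quasi-likelihood F-test and Benjamini-Hochberg adjustment, 3541 of 12411 genes changed, 1943 up and 1598 down, with Cish at adjusted p = 1.54e-14. That count was 2251 without SCF replicate 3 and 2276 without unstimulated replicate 2. Notch1 passed when only the compared groups were fitted (-0.24).

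Libraries labelled IL7 showed the opposite pair of responses: the ERK feedback genes rose, and the STAT5 feedback genes did not. Dusp6 (mm10 chromosome 10, 99263231 to 99267489) went from 2.28 ± 0.217 to 18.5 ± 3.16 CPM and Spred2, an inhibitor of the ERK pathway, from 1.11 ± 0.604 to 16.8 ± 5.37 CPM. Cish stood at 5.34 ± 0.546 CPM against 6.26 ± 0.774 unstimulated. Gem, which encodes a small GTPase, rose by 4.67 ± 0.40, Myc by 3.96 ± 0.14, the amino acid transporter gene Slc7a5 by 3.33 ± 0.29 and Etv5 by 2.38 ± 0.27. Falls included Il7r (-1.46 ± 0.08), Kit (-0.89 ± 0.09), Notch1 (-0.58 ± 0.14), Pten (-0.47 ± 0.09), the cytokine feedback gene Socs2 (-0.92 ± 0.16) and the phosphate transporter gene Slc34a3 (-1.87 ± 0.19). Tal1 did not pass (0.15 ± 0.13) and passed without IL7 replicate 3 (0.31). Mcpt4, a mast cell chymase gene with close paralogs that share reads, rose by 1.51 ± 0.30. Of 21 ERK and KIT feedback genes, 14 rose (14 adjusted over the list alone), with a median of 1.38 (camera adjusted p = 2.0e-13). IL7 and STAT5 target genes rose in 4 of 20 and fell in 7 (4 and 7 adjusted over the list alone), with a median of -0.11 (camera adjusted p = 0.66). All 25 ribosome biogenesis and MYC genes rose (25 adjusted over the list alone; median 1.45). Glycolysis genes rose in 13 of 20 and fell in 1 (13 and 1 adjusted over the list alone), with Hk2, a hexokinase gene, at 1.59 ± 0.10. Their camera call was lost, at adjusted p = 0.28 with an estimated correlation. Within groups, the median glycolysis gene changed by -0.0471 log2 per percentage point of the no-feature share, which was 44.9 ± 1.72% unstimulated and 34.2 ± 8.12% in the libraries labelled IL7. FOXO target genes fell in 13 of 29 and rose in 1 (14 and 1 adjusted over the list alone), with the death effector gene Bcl2l11 at -0.72 ± 0.07. This camera call was lost too, at adjusted p = 0.15 with an estimated correlation. The edgeR quasi-likelihood F-test with Benjamini-Hochberg adjustment called 5956 of 12411 genes, 3160 higher and 2796 lower, with Dusp6 at adjusted p = 2.15e-09. These libraries differed among themselves more than those of any other group, with a chi-square per degree of freedom of 31.2 to 98.15 between replicates (at most 28.4 in the others). Their no-feature shares were 25.9, 34.5 and 42.1%. That count was 2597 when only the compared groups were fitted. With the no-feature share as a covariate, chosen after the values were seen, it was 3611, and Mcpt4 lost its call (0.89).

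**Figure D1:**
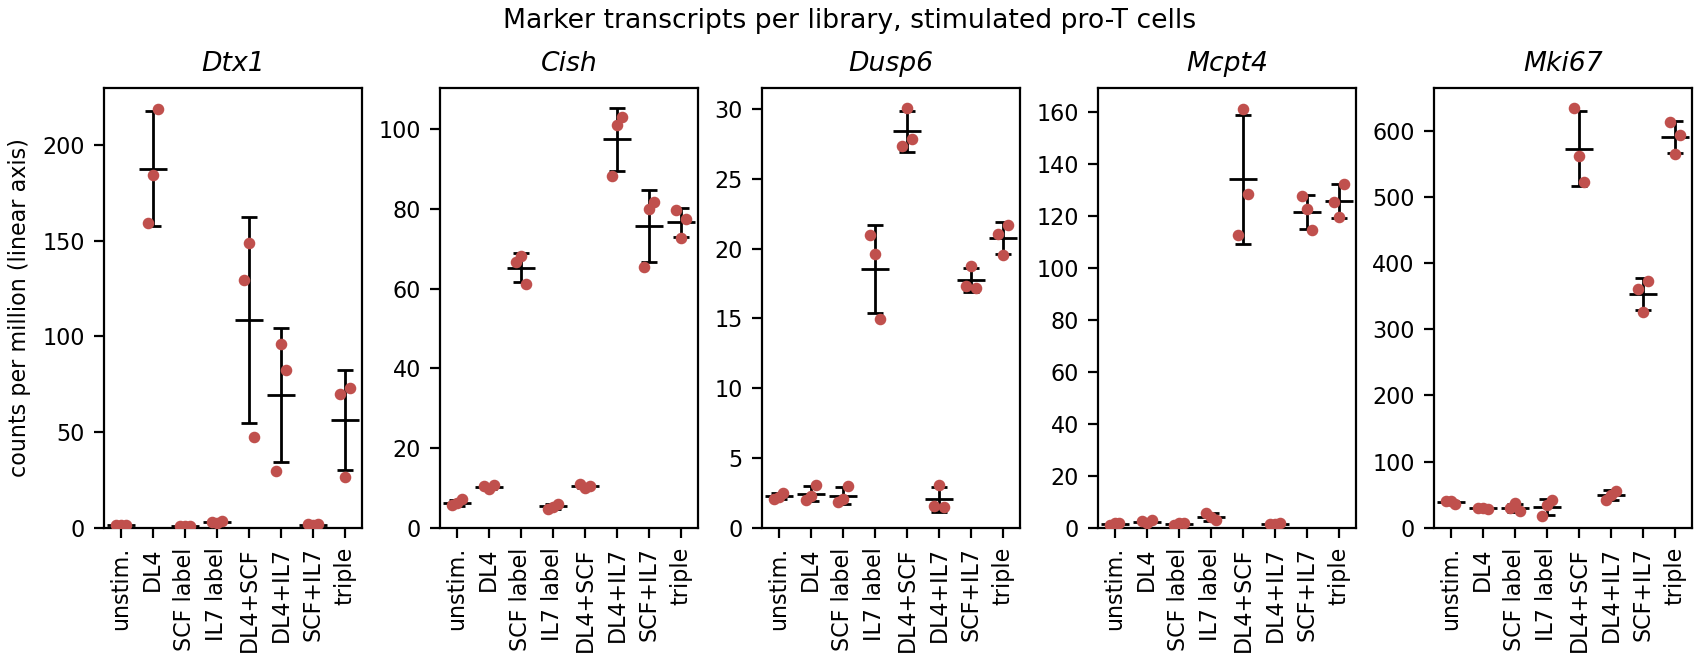
CPM (linear axes) of 5 genes in each library of the 8 stimulated groups, with the mean and SD of 3 libraries. Cish averaged 65.3 CPM in the libraries labelled SCF and 5.34 in those labelled IL7, Dusp6 averaged 2.31 and 18.5, and Mcpt4 and Mki67 were high in the groups with SCF plus another stimulus.

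DL4 plus SCF raised mast cell genes and cell cycle genes that neither single stimulation had raised to that level. Mcpt4 (mm10 chromosome 14, 56059629 to 56062313; its paralogs share reads) went from 1.48 ± 0.279 to 134 ± 24.8 CPM. Fcer1a, the alpha chain gene of the IgE receptor, went from 0.534 ± 0.138 to 22.0 ± 1.81 CPM, and Top2a, the topoisomerase of dividing cells, from 22.5 ± 1.04 to 321 ± 24.5 CPM. The transcription factor gene Gata2 rose by 2.46 ± 0.14, the IL-33 receptor gene Il1rl1 by 4.42 ± 0.21, and Rad51, a recombinational repair gene of S phase, by 5.56 ± 0.23. ERK feedback genes rose with them, Dusp6 by 3.65 ± 0.21 and Spred2 by 4.03 ± 0.28, while Pim2, a STAT5 target, fell by 1.80 ± 0.17. Notch1 (1.55 ± 0.14) and Il2ra (3.56 ± 0.22) rose, Kit (-0.47 ± 0.09), Pten (-0.58 ± 0.09) and S1pr1, a gene of thymic exit (-2.65 ± 0.17), fell, and Il7r (0.19 ± 0.08) and Tal1 (0.24 ± 0.12) did not pass. Il7r passed without DL4 plus SCF replicate 3 (0.23), in the DESeq2 Wald test (0.19), when only the compared groups were fitted (0.19), and with the no-feature share as a covariate, chosen after the values were seen (0.28). Tal1 passed when only the compared groups were fitted (0.24). Of 14 mast cell and basophil marker genes, 11 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 4.53, or 3.58 with the gene at 0 counts at its bound (camera adjusted p = 1.6e-14). All 25 G2 and M phase genes rose (25 adjusted over the list alone; median 3.53), as did all 25 S phase genes (25 adjusted over the list alone; median 2.35). ERK and KIT feedback genes rose in 14 of 21 (14 adjusted over the list alone; median 1.38). IL7 and STAT5 target genes rose in 7 of 20 and fell in 9 (7 and 9 adjusted over the list alone), with a median of -0.18 and a mean of 0.16. NOTCH target genes rose in 11 of 18 and fell in 5 (11 and 5 adjusted over the list alone), and their camera call was lost, at adjusted p = 0.16 with an estimated correlation. In the edgeR quasi-likelihood F-test with Benjamini-Hochberg adjustment, 6792 of 12411 genes changed, 3565 higher and 3227 lower, with Mcpt4 at adjusted p = 8.54e-15.

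DL4 plus IL7 raised STAT5 targets and some NOTCH targets, with little change in mast cell genes. Cish reached 97.4 ± 7.96 CPM, Dtx1 69.6 ± 35.1 CPM and Bcl2 1094 ± 118 CPM, against 6.26 ± 0.774, 1.55 ± 0.0977 and 316 ± 7.25 CPM unstimulated, while Mcpt4 stood at 1.46 ± 0.278 against 1.48 ± 0.279. Vat1l rose by 6.88 ± 0.31, the granzyme gene Gzmb by 5.81 ± 0.41, Myc by 4.84 ± 0.14, Notch1 by 0.92 ± 0.14 and Tal1 by 0.41 ± 0.13. Wfdc18 (-4.52 ± 0.52), the thymic homing receptor gene Ccr9 (-3.14 ± 0.25), Il7r (-1.81 ± 0.09), Kit (-0.37 ± 0.09) and Pten (-0.30 ± 0.09) fell. Of 20 IL7 and STAT5 target genes, 14 rose and 4 fell (15 and 4 adjusted over the list alone), with a median of 1.52 (camera adjusted p = 6.0e-16). NOTCH target genes rose in 9 of 18 and fell in 4 (9 and 4 adjusted over the list alone), with a median of 0.80, also with the gene at 0 counts at its bound. Their camera call was lost, at adjusted p = 0.13 with an estimated correlation. Cholesterol synthesis genes rose in 20 of 22 (20 adjusted over the list alone; median 1.12). G2 and M phase genes rose in 12 of 25 with 1 lower (12 and 1 adjusted over the list alone; median 0.62, Top2a at 1.29 ± 0.12). Mast cell and basophil marker genes rose in 2 of 14 and fell in 2 (0 and 2 adjusted over the list alone). They had a median of 0.17, or -0.03 with the gene at 0 counts at its bound, a mean of 0.36 and a camera direction down at adjusted p = 0.82. Erythroid and megakaryocyte marker genes rose in 3 of 6 and fell in 1 (3 and 1 adjusted over the list alone; median 0.49, camera adjusted p = 0.35). By edgeR quasi-likelihood F-test and Benjamini-Hochberg adjustment, 6582 of 12411 genes changed, 3450 up and 3132 down, and Cish had adjusted p = 4.01e-16. Tal1 lost its call (0.16) with the no-feature share as a covariate, chosen after the values were seen.

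SCF plus IL7, without DL4, gave STAT5, ERK, mast cell and cell cycle responses in the same libraries. Cish reached 75.7 ± 9.03 CPM, Dusp6 17.8 ± 0.874, Mcpt4 122 ± 6.62 and Top2a 230 ± 8.88 CPM, from 6.26 ± 0.774, 2.28 ± 0.217, 1.48 ± 0.279 and 22.5 ± 1.04 CPM unstimulated. The early response gene Egr1 rose by 5.70 ± 0.52, the chymase gene Cma1 by 5.72 ± 0.30, Cad, a gene of pyrimidine synthesis, by 2.38 ± 0.09 and Slc7a1, an arginine transporter gene, by 3.08 ± 0.11. Il7r (-2.17 ± 0.09), the repressor gene Bcl6 (-1.68 ± 0.07), the guidance receptor gene Robo3 (-3.23 ± 0.17), Kit (-0.92 ± 0.09) and Pten (-0.58 ± 0.09) fell, and Notch1 did not pass (0.01 ± 0.14). Tal1 rose by 0.33 ± 0.12, a call lost without SCF plus IL7 replicate 2 (0.31) or 3 (0.30) and without unstimulated replicate 1 (0.33) or 2 (0.28). It stood at -0.01 with the no-feature share as a covariate, chosen after the values were seen. Of 20 IL7 and STAT5 target genes, 15 rose and 4 fell (15 and 4 adjusted over the list alone; median 1.64), and of 21 ERK and KIT feedback genes, 18 rose (18 adjusted over the list alone; median 1.78). Mast cell and basophil marker genes rose in 11 of 14 and fell in 1 (12 and 1 adjusted over the list alone), with a median of 5.08, or 4.39 with the gene at 0 counts at its bound. All 25 G2 and M phase genes rose (25 adjusted over the list alone; median 3.19), and FOXO target genes fell in 20 of 29 and rose in 3 (20 and 3 adjusted over the list alone; median -0.62). Myeloid marker genes split into 7 higher and 7 lower of 18 (7 and 7 adjusted over the list alone), with a median of 0.14, a mean of 0.30 and a camera direction down at adjusted p = 0.83. NK and innate lymphoid marker genes rose in 7 of 12 and fell in 4 (7 and 4 adjusted over the list alone; median 1.18, camera adjusted p = 0.37). The edgeR quasi-likelihood F-test with Benjamini-Hochberg adjustment called 8081 of 12411 genes, 4316 higher and 3765 lower, with Mcpt4 at adjusted p = 1.22e-14.

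All 3 stimuli together changed the most genes of the 7 stimulations compared with unstimulated cells. Myc went from 7.74 ± 0.677 to 344 ± 24.9 CPM, Top2a from 22.5 ± 1.04 to 419 ± 38.8, Mcpt4 from 1.48 ± 0.279 to 126 ± 6.51 and Cish from 6.26 ± 0.774 to 76.7 ± 3.60 CPM. Rad51 rose by 6.02 ± 0.22, the serine synthesis gene Psat1 by 3.86 ± 0.19, Dusp6 by 3.19 ± 0.21, Gata2 by 2.46 ± 0.14, Notch1 by 0.72 ± 0.14 and Tal1 by 0.62 ± 0.12. Wfdc18 (-5.59 ± 0.57), the thrombospondin gene Thbs1 (-4.64 ± 0.26), the chemokine gene Ccl4 (-4.12 ± 0.16), Ccr9 (-4.14 ± 0.27), S1pr1 (-3.91 ± 0.19) and the T cell kinase gene Itk (-2.49 ± 0.14) fell. Il7r (-2.25 ± 0.09), Kit (-1.12 ± 0.09) and Pten (-0.84 ± 0.09) fell as well. All 25 G2 and M phase genes (median 3.88), all 25 S phase genes (median 2.79) and all 25 ribosome biogenesis and MYC genes (median 2.33) rose, each with 25 adjusted over the list alone. FOXO target genes fell in 21 of 29 and rose in 4 (21 and 4 adjusted over the list alone; median -0.86), with the pro-death gene Bmf, on the apoptosis list, at -2.48 ± 0.15. Mast cell and basophil marker genes rose in 11 of 14 and fell in 2 (11 and 2 adjusted over the list alone), with a median of 4.44, or 3.45 with the gene at 0 counts at its bound. NOTCH target genes rose in 11 of 18 and fell in 6 (11 and 6 adjusted over the list alone; median 0.93, also with the gene at 0 counts at its bound, camera adjusted p = 0.34). Early T lineage genes fell in 10 of 21 and rose in 6 (10 and 6 adjusted over the list alone). They had a median of -0.31, also with the gene at 0 counts at its bound, a mean of 0.13 and a camera direction down at adjusted p = 0.068. B lineage marker genes rose in 2 of 6 and fell in 3 (2 and 3 adjusted over the list alone; median -0.02, camera adjusted p = 0.73). Both tested fibroblast stroma marker genes had a median of -2.41, with 1 fallen (2 adjusted over the list alone). In the edgeR quasi-likelihood F-test with Benjamini-Hochberg adjustment, 9018 of 12411 genes changed, 4642 higher and 4376 lower, with Top2a at adjusted p = 8.78e-16.

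**Figure D2:**
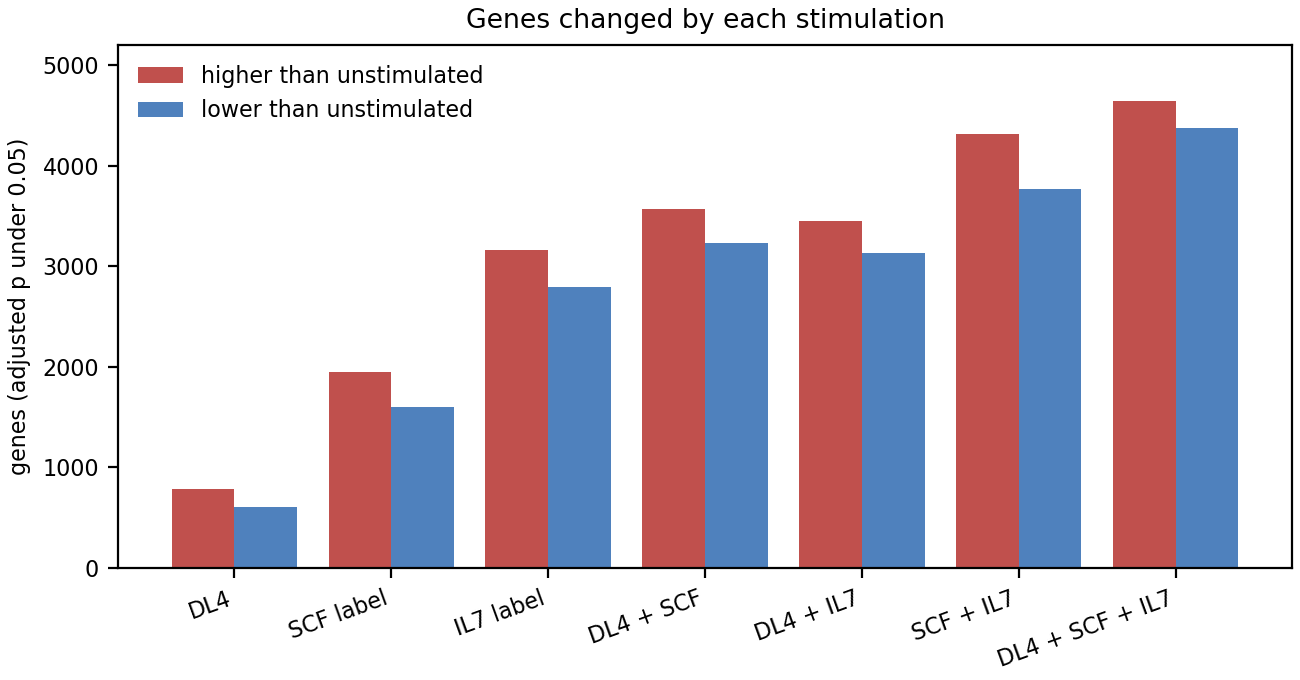
Number of genes (axis from 0) higher and lower than in unstimulated cells at an adjusted p under 0.05, for the 7 stimulations. Counts run from 785 higher and 603 lower with DL4 to 4642 higher and 4376 lower with the 3 stimuli together.

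The interaction of DL4 and SCF, the part of the joint response beyond the sum of the single responses on the log2 scale, was positive for cell cycle genes and several mast cell genes. Cenpf, a kinetochore gene, stood at 95.3 ± 7.16 CPM with DL4 plus SCF, against 4.94 ± 0.369 with DL4, 4.87 ± 0.388 in the libraries labelled SCF and 7.05 ± 1.15 unstimulated, an interaction of 4.81 ± 0.20. The S phase regulator gene E2f1 had 2.50 ± 0.18, Gata2 2.93 ± 0.23, Mcpt4 5.89 ± 0.51 and Etv5 5.74 ± 0.62. Negative values included genes raised in the libraries labelled SCF: Lrrc32 had -6.52 ± 0.73, Cish -3.36 ± 0.16, the STAT5 feedback gene Socs1 -3.12 ± 0.21 and Myc -2.16 ± 0.17. Il7r had 1.68 ± 0.12, and Kit did not pass (-0.08 ± 0.12). All 25 G2 and M phase genes had a positive interaction (25 adjusted over the list alone; median 4.26). IL7 and STAT5 target genes had 13 negative and 1 positive of 20 (14 and 1 adjusted over the list alone; median -1.25). For cholesterol synthesis genes, 14 of 22 were negative (17 adjusted over the list alone; median -0.67), and the camera call was lost, at adjusted p = 0.12 with an estimated correlation. For p53 target genes, 6 of 21 were negative and 1 positive (10 and 1 adjusted over the list alone), and that camera call was also lost, at adjusted p = 0.099 with an estimated correlation. With Benjamini-Hochberg adjustment, the edgeR quasi-likelihood F-test called 2230 genes, 1149 positive and 1081 negative, with Cenpf at adjusted p = 1.54e-12. Each value rests on the single stimulations as labelled. The interactions of Timp3 (-5.80 ± 1.21, a metalloproteinase inhibitor gene, no longer called without DL4 replicate 2), Vat1l (-5.14 ± 0.58) and Cish turned positive when the SCF and IL7 labels were exchanged (0.63, 0.14 and 0.25), an alternative chosen after the values were seen. Lrrc32 (-0.76) and Etv5 (0.51) lost their calls in it, and the count was 3128, 1475 positive and 1653 negative. With the no-feature share as a covariate, also chosen afterwards, the count was 3736.

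For DL4 and IL7, most STAT5 target genes had positive interactions and some ERK genes negative ones. Cish stood at 97.4 ± 7.96 CPM with DL4 plus IL7, against 10.3 ± 0.527 with DL4, 5.34 ± 0.546 in the libraries labelled IL7 and 6.26 ± 0.774 unstimulated, an interaction of 3.46 ± 0.17. Pim2 had 3.63 ± 0.23, Socs2 3.29 ± 0.22, Vat1l 5.60 ± 0.85 and the imprinted RNA gene H19 5.44 ± 0.69. Dusp6 had -3.32 ± 0.35, Spred2 -2.75 ± 0.52, Myc -2.12 ± 0.17, the ribosome biogenesis gene Nop2 -0.72 ± 0.10, Il7r -1.09 ± 0.12 and Mcpt4 -2.20 ± 0.44, and Pten had 0.52 ± 0.12. Of 20 IL7 and STAT5 target genes, 14 were positive and 3 negative (15 and 4 adjusted over the list alone; median 1.30, camera adjusted p = 2.8e-18). ERK and KIT feedback genes had 9 negative and 2 positive of 21 (10 and 2 adjusted over the list alone; median -1.35), and the camera call was lost, at adjusted p = 0.085 with an estimated correlation. Ribosome biogenesis and MYC genes had 15 of 25 negative (16 adjusted over the list alone; median -0.55), with the camera call lost at adjusted p = 0.29 with an estimated correlation. By edgeR quasi-likelihood F-test and Benjamini-Hochberg adjustment, 2673 genes passed, 1348 positive and 1325 negative, with Cish at adjusted p = 1.68e-11. The count was 4573 without IL7 replicate 3 and 1393 when only the compared groups were fitted, where Pten (0.48) lost its call. With the SCF and IL7 labels exchanged, chosen after the values were seen, it was 476. There Cish (-0.15) and Spred2 (0.52) changed sign, and Vat1l (0.32), H19 (0.59), Socs2 (0.71), Dusp6 (-0.32), Il7r (-0.33), Mcpt4 (-0.62) and Pten (0.21) lost their calls.

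SCF and IL7 together gave positive interactions for genes of cell division. Cenpf stood at 58.9 ± 2.11 CPM with SCF plus IL7, against 4.87 ± 0.388 in the libraries labelled SCF, 2.92 ± 0.70 in those labelled IL7 and 7.05 ± 1.15 unstimulated, an interaction of 4.86 ± 0.20. Neil3, a DNA glycosylase gene of S phase, had 6.30 ± 0.47, the mitotic kinesin gene Kif18b 6.28 ± 0.68, Top2a 3.23 ± 0.18, Mcpt4 4.93 ± 0.48 and Gata2 2.53 ± 0.22. Some genes that both single stimulations had raised had negative values: Myc -2.75 ± 0.17, Asns -2.75 ± 0.38, the tRNA methyltransferase gene Mettl1 -3.00 ± 0.33 and the glycine transporter gene Slc6a9 -2.97 ± 0.21. Il7r (1.503 ± 0.12), Notch1 (0.85 ± 0.20) and Kit (0.55 ± 0.12) were positive. All 25 G2 and M phase genes were positive (25 adjusted over the list alone; median 3.78), as were 20 of 25 S phase genes (20 adjusted over the list alone; median 1.53). Positive too were 8 of 14 mast cell and basophil marker genes (9 adjusted over the list alone; median 2.90). TAL1 and GATA complex genes were positive in 7 of 23 (7 adjusted over the list alone; median 0.29, camera adjusted p = 0.011). Ribosome biogenesis and MYC genes were negative in 14 of 25 (15 adjusted over the list alone; median -0.60), and the camera call was lost, at adjusted p = 0.083 with an estimated correlation. With Benjamini-Hochberg adjustment, the edgeR quasi-likelihood F-test called 2042 genes, 1121 positive and 921 negative, with Neil3 at adjusted p = 4.52e-09. This count was 3469 without IL7 replicate 3, 1146 when only the compared groups were fitted, where Kit (0.52) lost its call, and 3765 with the no-feature share as a covariate, chosen after the values were seen.

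The planned overlap asked whether SCF and IL7 acted on the same genes, with no library shared. Of 12411 genes, 1156 rose and 811 fell both in the libraries labelled SCF against unstimulated and in DL4 plus IL7 against DL4, where 343.5 and 238.3 were expected from independent calls. Another 32 went opposite ways (572 expected). Across genes, which are not independent replicates, the fold changes had a Pearson r of 0.67 and a Spearman rho of 0.60. With the libraries labelled IL7 in their place, chosen after the values were seen, 1049 rose and 859 fell in both, 329 went opposite ways, and r was 0.34 and rho 0.40. Adding SCF to DL4 gave an ERK and KIT feedback median of 1.03 and an IL7 and STAT5 median of -0.21, and adding IL7 to DL4 gave 0.34 and 1.18.

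**Figure D3:**
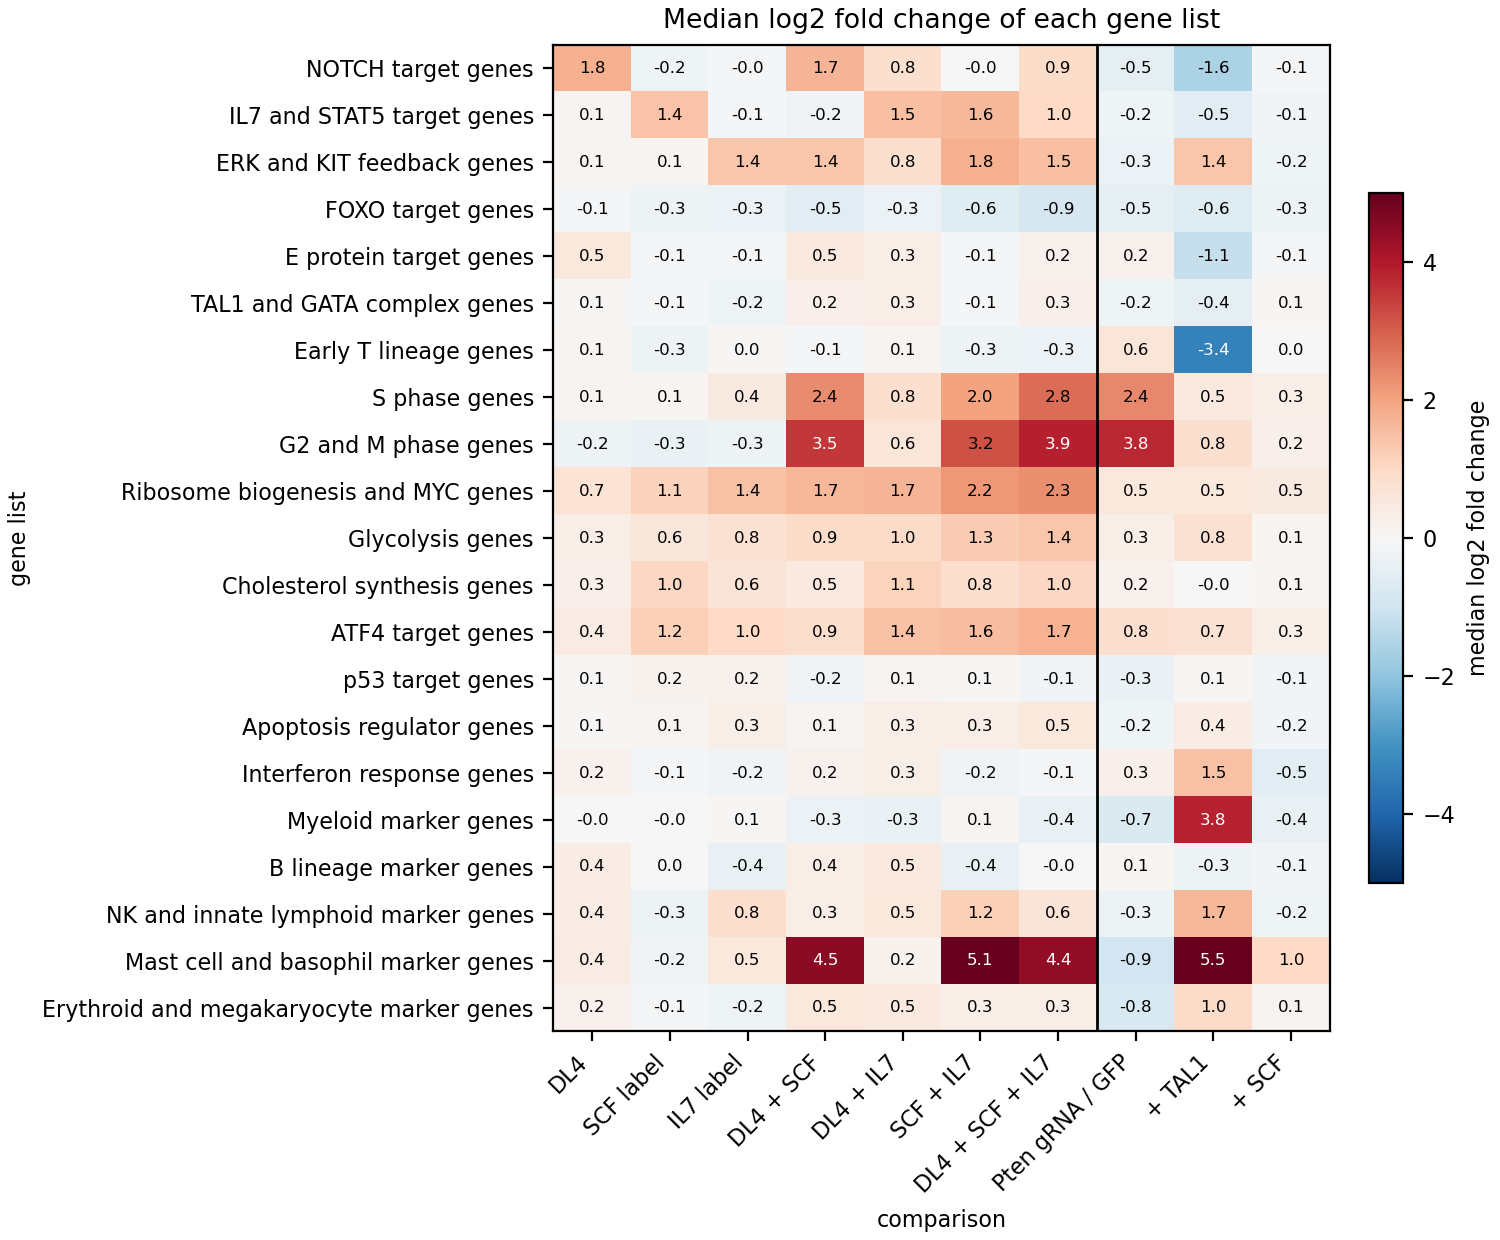
Median log2 fold change of each gene list, except the fibroblast stroma marker genes, in 10 comparisons. The colour scale runs from -5 to 5, with values above it shown in the darkest colour. Compared are 7 stimulations against unstimulated, Pten gRNA against GFP, TAL1 in Pten gRNA cells and SCF in Pten gRNA and TAL1 cells. IL7 and STAT5 target genes have a median of 1.41 in the libraries labelled SCF and -0.11 in those labelled IL7, and early T lineage genes of -3.38 with TAL1.

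In the transduced experiment, Pten was read first as the gene targeted by the guide. It stood at 592, 623 and 634 CPM in the 3 GFP libraries, at 1192, 1053 and 1060 in the libraries labelled Pten gRNA, at 329, 313 and 309 with TAL1, and at 267, 258 and 248 with TAL1 and SCF. Gene-level counts cannot show editing, which need not lower a transcript, so every direction given for these libraries is that of the libraries labelled Pten gRNA. Tal1 averaged 22.5 ± 0.488 CPM with GFP, 8.36 ± 0.382 with Pten gRNA, 96.1 ± 42.8 with TAL1 (64.6, 78.9 and 145 by library) and 75.5 ± 5.79 with TAL1 and SCF. These counts would hold reads from a vector only as far as its sequence aligned to the mouse gene.

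**Figure D4:**
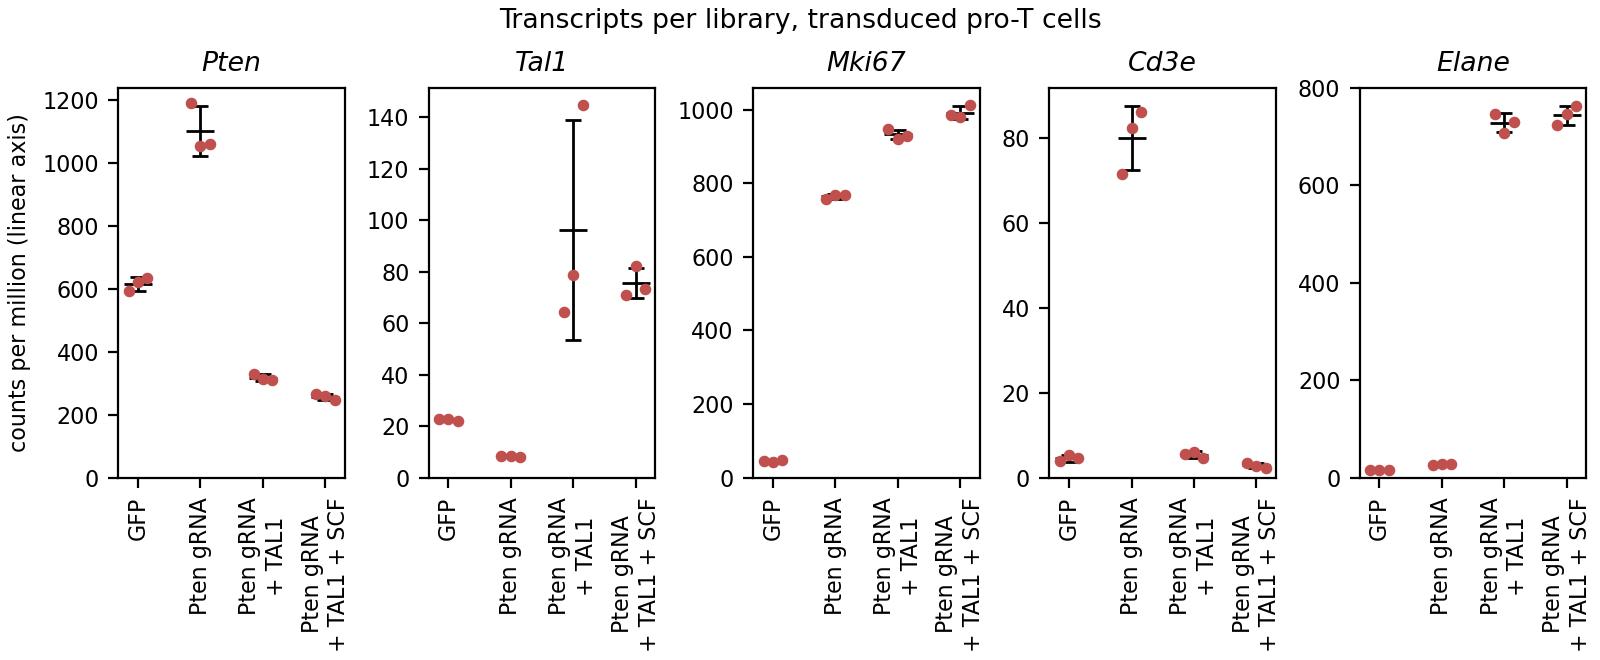
CPM (linear axes) of 5 genes in each library of the 4 transduced groups, with the mean and SD of 3 libraries. Pten was highest in the Pten gRNA libraries (1102 CPM), Mki67 averaged 45.7 CPM with GFP and 764 to 992 in the other 3 groups, and Cd3e averaged 80.1 CPM with Pten gRNA and 5.40 with TAL1.

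Compared with GFP, the libraries labelled Pten gRNA had far more RNA of dividing cells, and most early T lineage genes were higher and most myeloid marker genes lower. Mki67, the proliferation marker, went from 45.7 ± 3.14 to 764 ± 6.74 CPM, and Dntt, the terminal transferase gene of T cell receptor rearrangement, from 41.3 ± 0.787 to 484 ± 38.8 CPM. Cd3e, a T cell receptor chain gene, went from 4.57 ± 0.798 to 80.1 ± 7.62 CPM, and Camp, a granule peptide gene, from 95.1 ± 1.20 to 2.70 ± 0.189 CPM, whereas the neutrophil elastase gene Elane went from 15.1 ± 0.389 to 27.4 ± 1.57 CPM. Rrm2, a nucleotide reductase gene, rose by 4.67 ± 0.09, Tox2 by 6.24 ± 0.33, Psat1 by 2.22 ± 0.08 and Pten by 0.84 ± 0.05. Igf2, the imprinted growth factor gene, had -7.24 ± 0.09 (its antisense gene shares its locus), the neutrophil gene Retnlg -8.92 ± 0.17, Klf2, a quiescence factor gene, -2.14 ± 0.07 and Pim2 -3.00 ± 0.07. Kit (-0.94 ± 0.04), Il7r (-0.40 ± 0.04), Notch1 (-0.46 ± 0.06) and Tal1 (-1.42 ± 0.25) fell. All 25 G2 and M phase genes rose (25 adjusted over the list alone; median 3.76, camera adjusted p = 8.2e-93), and so did all 25 S phase genes (25 adjusted over the list alone; median 2.42). Early T lineage genes rose in 16 of 22 and fell in 5, Cd7 among them at -1.75 ± 0.05 (16 and 5 adjusted over the list alone; median 0.61). Myeloid marker genes fell in 17 of 20 and rose in 2 (17 and 2 adjusted over the list alone; median -0.72). FOXO target genes fell in 22 of 29 and rose in 5 (22 and 5 adjusted over the list alone; median -0.45), and the camera call was lost, at adjusted p = 0.13 with an estimated correlation. For p53 target genes, 18 of 25 fell and 3 rose (18 and 3 adjusted over the list alone; median -0.32), with the camera call lost at adjusted p = 0.13 with an estimated correlation. Apoptosis regulator genes fell in 9 of 19 and rose in 5 (9 and 5 adjusted over the list alone), with a median of -0.21, or -0.18 with the gene at 0 counts at its bound (camera adjusted p = 0.12). In the edgeR quasi-likelihood F-test with Benjamini-Hochberg adjustment, 10069 of 14909 genes changed, 5009 higher and 5060 lower, with Mki67 at adjusted p = 1.66e-22.

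Libraries with Pten gRNA and TAL1 differed from GFP by a gain of myeloid genes and a loss of T lineage genes. Elane, the neutrophil elastase gene (mm10 chromosome 10, 79886247 to 79888215), went from 15.1 ± 0.389 to 728 ± 19.4 CPM. Csf1r, the receptor gene of macrophage growth, went from 30.9 ± 1.92 to 992 ± 20.5 CPM, and Lck, the T cell receptor kinase gene, from 499 ± 4.52 to 46.9 ± 1.21 CPM. Id2, an inhibitor of E proteins, rose by 3.85 ± 0.05, the cyclin gene Ccnd1 by 4.17 ± 0.07, Mki67 by 4.35 ± 0.05 and Tal1 by 2.10 ± 0.19. The T cell receptor zeta chain gene Cd247 had -6.24 ± 0.08, Notch3 -6.02 ± 0.11, and Tcf7, a T lineage factor gene, -3.22 ± 0.05. Pten (-0.96 ± 0.05), Kit (-2.10 ± 0.04), Il7r (-0.39 ± 0.04) and Notch1 (-1.03 ± 0.06) fell. All 20 myeloid marker genes rose (20 adjusted over the list alone; median 2.01). Early T lineage genes fell in 19 of 22 and rose in 2 (19 and 2 adjusted over the list alone; median -2.63, camera adjusted p = 4.3e-17). Interferon response genes rose in 21 of 23 (21 and 1 lower adjusted over the list alone; median 1.99), and the camera call was lost, at adjusted p = 0.17 with an estimated correlation. NOTCH target genes fell in 11 of 15 and rose in 4 (11 and 4 adjusted over the list alone; median -1.73), with the camera call lost at adjusted p = 0.066 with an estimated correlation. By edgeR quasi-likelihood F-test and Benjamini-Hochberg adjustment, 12609 of 14909 genes changed, 6358 up and 6251 down, with Elane at adjusted p = 2.65e-24. Tal1 lost its call, at 0.23, with the no-feature share as a covariate, chosen after the values were seen.

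With SCF added to Pten gRNA and TAL1, myeloid genes again lay far above GFP. Elane stood at 744 ± 19.2 CPM and Csf1r at 686 ± 18.4, against 15.1 ± 0.389 and 30.9 ± 1.92 with GFP, and Igf2 at 0.107 ± 0.0680 against 671 ± 13.3. Srm, a polyamine synthesis gene, rose by 3.07 ± 0.05, Psat1 by 3.81 ± 0.07, Mki67 by 4.44 ± 0.05 and Tal1 by 1.75 ± 0.20. Cd247 (-6.13 ± 0.08), the adaptor gene Lat (-3.64 ± 0.05), Klhl24, a FOXO target (-2.99 ± 0.04), Pten (-1.26 ± 0.05), Kit (-1.98 ± 0.04), Il7r (-1.17 ± 0.04) and Notch1 (-1.38 ± 0.06) fell. All 20 myeloid marker genes rose (20 adjusted over the list alone; median 1.74), as did all 25 ribosome biogenesis and MYC genes (25 adjusted over the list alone; median 1.53). FOXO target genes fell in 25 of 29 and rose in 2 (25 and 2 adjusted over the list alone; median -1.44). For the ribosome biogenesis and MYC genes the camera call was lost, at adjusted p = 0.080 with an estimated correlation. The edgeR quasi-likelihood F-test with Benjamini-Hochberg adjustment called 12878 of 14909 genes, 6376 higher and 6502 lower, with Elane at adjusted p = 3.00e-24. With the no-feature share as a covariate, chosen after the values were seen, 7863 genes passed and Tal1 stood at -0.89.

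Libraries with Pten gRNA and TAL1 had lower T lineage and higher myeloid transcripts than those with Pten gRNA alone. Sample titles call these TAL1 libraries unstimulated and give no stimulation state for the Pten gRNA or GFP ones. Cish stood at 49.2 to 52.2 CPM with Pten gRNA and at 36.1 to 37.25 with TAL1. A difference in stimulation state cannot be told apart from TAL1 in this comparison. Camp went from 2.70 ± 0.189 to 295 ± 19.7 CPM, and the granulocyte calcium-binding gene S100a9 from 58.8 ± 5.03 to 3180 ± 260 CPM. Dntt went from 484 ± 38.8 to 2.23 ± 0.216 and the recombinase gene Rag1 (mm10 chromosome 2, 101638282 to 101649501) from 61.0 ± 1.75 to 0.0590 ± 0.0673 CPM. Tal1 rose by 3.52 ± 0.22, the complement gene C1qa by 8.60 ± 0.20, Mertk, a receptor of macrophages for dying cells, by 8.93 ± 0.21, and the AP-1 gene Fos by 3.33 ± 0.07. Notch3 had -7.53 ± 0.09, Bcl11b, a T lineage commitment factor gene, -3.49 ± 0.05, and Gzma, a cytotoxic granule gene, -9.76 ± 0.15. Pten (-1.80 ± 0.05), Kit (-1.16 ± 0.04) and Notch1 (-0.58 ± 0.06) fell, and Il7r did not pass (0.02 ± 0.04). Early T lineage genes fell in 21 of 22 and rose in 1 (21 and 1 adjusted over the list alone; median -3.38, camera adjusted p = 3.5e-36). All 20 myeloid marker genes rose (20 adjusted over the list alone; median 3.85, camera adjusted p = 4.7e-57). E protein target genes fell in 18 of 23 and rose in 4 (18 and 4 adjusted over the list alone, median -1.15). This list shares Cd3e, Cd3d, Cd3g, Dntt, Ptcra, Cd28 and Cd5 with the early T lineage list, so its fall is not a separate result. Interferon response genes rose in 22 of 23 (22 adjusted over the list alone; median 1.46, Oasl2 at 2.71 ± 0.06), and the camera call was lost, at adjusted p = 0.21 with an estimated correlation. ERK and KIT feedback genes rose in 15 of 21 and fell in 2 (15 and 2 adjusted over the list alone; median 1.39), with the camera call lost at adjusted p = 0.075 with an estimated correlation. Mast cell and basophil marker genes rose in 10 of 13, Hdc at 3.31 ± 0.08, and fell in 3, Cpa3 at -2.40 ± 0.05 (10 and 3 adjusted over the list alone). They had a median of 5.53 (or 4.63 with the gene at 0 counts at its bound), with camera adjusted p = 0.092. Among TAL1 and GATA complex genes, 8 of 23 rose and 12 fell (8 and 12 adjusted over the list alone; median -0.45, camera adjusted p = 0.12). In the edgeR quasi-likelihood F-test with Benjamini-Hochberg adjustment, 11738 of 14909 genes changed, 5927 higher and 5811 lower, with Camp at adjusted p = 2.67e-24.

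SCF in Pten gRNA and TAL1 cells changed many genes by small amounts, with mast cell genes among its largest rises. Mcpt4 went from 3.72 ± 0.536 to 13.2 ± 1.35 CPM, the basophil protease gene Mcpt8 from 17.3 ± 0.421 to 38.2 ± 1.34, and Csf1r from 992 ± 20.5 to 686 ± 18.4 CPM (paralogs of the Mcpt family share reads). Cox6a2, a respiratory chain subunit gene, rose by 1.86 ± 0.09, Tpsb2, a tryptase gene with the close paralog Tpsab1, by 1.79 ± 0.12. Gata2 rose by 1.01 ± 0.12, Srm by 0.78 ± 0.05, Myc by 0.70 ± 0.05 and Kit by 0.12 ± 0.04. Igf1 (-1.06 ± 0.10), the interferon-induced gene Oasl2 (-0.76 ± 0.06), Il7r (-0.78 ± 0.04), Pten (-0.30 ± 0.05) and Notch1 (-0.35 ± 0.06) fell. Unc5b, a netrin receptor gene, fell by 1.36 ± 0.35, or by 0.55 without TAL1 replicate 1. Tal1 did not pass (-0.35 ± 0.17), passed with no filter (-0.29) and without TAL1 replicate 1 (-0.57), and stood at 0.08 without TAL1 replicate 3. The rise of Kit lost its call without TAL1 replicate 2 or 3 (both 0.11) and without TAL1 and SCF replicate 2 or 3 (both 0.12). Mast cell and basophil marker genes rose in 11 of 13 (11 adjusted over the list alone; median 1.01), and all 25 ribosome biogenesis and MYC genes rose (25 adjusted over the list alone; median 0.46). Interferon response genes fell in 21 of 23 (21 adjusted over the list alone; median -0.53), and the camera call was lost, at adjusted p = 0.11 with an estimated correlation. Myeloid marker genes fell in 13 of 20 and rose in 4 (13 and 4 adjusted over the list alone; median -0.39), with the camera call lost at adjusted p = 0.15 with an estimated correlation. ERK and KIT feedback genes rose in 3 of 21 and fell in 10 (3 and 11 adjusted over the list alone; median -0.21, camera adjusted p = 0.34). The edgeR quasi-likelihood F-test with Benjamini-Hochberg adjustment called 6903 of 14909 genes, 3051 higher and 3852 lower, with 200 changed at least 2-fold. The balance of directions turned in a pair of alternatives, with the cause not tested: 3678 rose and 3056 fell with no filter, and 4070 rose and 3331 fell when only the compared groups were fitted. With the stricter filter, 2974 rose and 3919 fell. With the no-feature share as a covariate, chosen after the values were seen, Unc5b stood at 0.90, Kit lost its call (0.08) and Tal1 passed (-1.12).

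The response to SCF in the transduced cells differed from that of the untransduced libraries labelled SCF. It was tested as a difference of differences over 12403 genes matched by symbol. Cish responded by 3.39 ± 0.12 in the libraries labelled SCF, and the difference was -3.82 ± 0.13. Without SCF, Cish already stood at 36.1 to 37.25 CPM in the Pten gRNA and TAL1 libraries, against 5.58 to 7.10 CPM in unstimulated cells. The responses thus started from unlike levels, and how far this shaped the difference was not tested. Lrrc32 had -6.38 ± 0.35, Myc -3.07 ± 0.10, the IL-4 receptor gene Il4ra -1.63 ± 0.09, Asns -3.49 ± 0.26 and the low-density lipoprotein receptor gene Ldlr -1.16 ± 0.07. Slc22a3, an organic cation transporter gene, had 2.42 ± 0.12, Mcpt4 1.87 ± 0.39, Il7r 1.40 ± 0.08, Kit 0.66 ± 0.10 and Etv5 2.62 ± 0.52. IL7 and STAT5 target genes had 14 negative and 2 positive of 20 (16 and 2 adjusted over the list alone; median -1.40, camera adjusted p = 1.2e-48). Cholesterol synthesis genes were negative in 20 of 22 (21 adjusted over the list alone; median -1.02), and mast cell and basophil marker genes positive in 6 of 13 (7 adjusted over the list alone; median 1.03). By edgeR quasi-likelihood F-test and Benjamini-Hochberg adjustment, 2050 genes passed, 662 positive and 1388 negative, or 900 and 1100 with DESeq2 size factors, with Cish at adjusted p = 1.28e-09. The cells and the experiment cannot be separated in this contrast, and the count was 3965 with the no-feature share as a covariate, chosen after the values were seen. With the libraries labelled IL7 in place of those labelled SCF, also chosen afterwards, it was 1706. There Etv5 (-2.60) and Cma1 (-0.04, from 2.11 ± 0.40) changed sign, and Cish (-0.21), Lrrc32 (-0.62) and Mcpt4 (0.30) lost their calls.

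Planned overlaps between the experiments used 11449 genes tested in both. Of these genes, 1059 rose and 700 fell both in the libraries labelled SCF and with SCF in Pten gRNA and TAL1 cells, against 453 and 392 expected from independent calls, and 330 went opposite ways (850 expected). The fold changes had a Pearson r of 0.29 and a Spearman rho of 0.43 across genes. The libraries labelled IL7 in their place, chosen after the values were seen, gave 1710, 1177 and 508, with r of 0.36 and rho of 0.46. The libraries labelled Pten gRNA shared 1092 rises and 728 falls with those labelled SCF (701.8 and 503.5 expected, 803 opposite) and 1843 rises and 1356 falls with those labelled IL7 (1156 and 874 expected, 1058 opposite). The expected opposite numbers were 1189 and 2011. At an absolute log2 fold change of at least 1 the balance with the libraries labelled SCF turned, with 74 shared rises, 20 shared falls and 119 opposite (30.6, 8.36 and 43 expected). With those labelled IL7 these were 110, 76 and 84 (45.4, 19.8 and 70 expected). Fold changes of the Pten gRNA comparison correlated across genes at r of 0.016 and rho of 0.23 with the libraries labelled SCF, and at 0.17 and 0.31 with those labelled IL7.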

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

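Every test in this part was chosen after the result was seen, except the splits of the samples and the tests of genomic DNA and sequencing depth.

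Tests of the difference itself singled out 4 results. Genes with an interaction of DL4 and SCF numbered 2230, of DL4 and IL7 2673, and of SCF and IL7 2042. The response to SCF in Pten gRNA and TAL1 cells differed from that of the libraries labelled SCF in 2050 genes. That difference rests on the SCF label of the untransduced libraries. Cish also started from a higher level in the transduced cells, as given above. With the libraries labelled IL7 in their place, Cish went from -3.82 to -0.21. Splits of the libraries of the 4 groups tested these counts. For DL4 and SCF, 4 of 100 splits gave as many genes (2386 in this fit, highest other 4022), for DL4 and IL7 1 of 100 (1393, highest other 1196), for SCF and IL7 2 of 100 (1146, highest other 2275), and for the SCF difference 3 of 100 (2050, highest other 5600). At these shares under 0.05, chance can be excluded only in the sense that the 4 groups differ in some way. The other splits mix the groups' own effects into the contrast, so they do not test the interaction by itself. Their highest counts of 4022, 2275 and 5600 genes exceeded the real ones, with the cause not tested.

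For comparisons of 2 groups, 3 against 3 libraries make 10 splits, too few for a share under 0.05. In each, only 1 split, the real one, gave as many genes. Real values were 1388 for DL4, 3541 for SCF, 6792 for DL4 plus SCF, 6582 for DL4 plus IL7, 8081 for SCF plus IL7, 9018 for the 3 stimuli, and 10069, 12609, 12878, 11738 and 6903 for the transduced comparisons, each with a highest other of 0. For IL7 it was 5956, with a highest other of 1496.

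The first pattern was that the libraries labelled SCF carried the STAT5 response and those labelled IL7 the ERK response. The median of IL7 and STAT5 target genes was 1.41 with the SCF label and -0.11 with the IL7 label, whereas it was -0.21 when SCF was added to DL4 and 1.18 when IL7 was. Exchanged labels of DL4 plus SCF and DL4 plus IL7 are argued against by mast cell genes 4.61 higher with DL4 plus SCF. This takes mast cell genes as a mark of SCF, because SCF raised them in the Pten gRNA and TAL1 cells. With the single SCF label Mcpt4 stood at 0.889 to 1.77 CPM, against 1.16 to 1.66 unstimulated and 2.82 to 5.775 with the IL7 label. A response to SCF that needs DL4 for its ERK genes stays open: SCF plus IL7 without DL4 exceeded the SCF label by 1.68 in their median, but the IL7 label alone raised that median by 1.38, so the excess need not come from SCF. Exchanged labels of the single stimulations stay a candidate explanation: across genes, the fold changes of 4 of 6 libraries correlated more with the other cytokine added to DL4, all 3 with the SCF label (r of 0.62 to 0.69 against 0.22 to 0.26) and 1 of 3 with the IL7 label (0.372 against 0.322, the others 0.260 against 0.296 and 0.340 against 0.371). Against the cytokine added to DL4 plus the other one, the same 4 libraries lay closer to the other cytokine. IL7 replicates 1 and 2 lay closer to their own (0.532 against 0.413 and 0.537 against 0.438). Yet in these 2 Cish stood at 4.81 and 5.30 CPM (88.3 to 103 with DL4 plus IL7). Dusp6 stood at 21 and 19.6 (2.09 to 2.52 unstimulated). Their no-feature shares were low (25.9 and 34.5%), and the share also fell from DL4 plus SCF (39.6%) to the 3 stimuli (34.0%). These correlations can follow that share, so they cannot decide on an exchange of these 2. A biological difference between single and joint stimulation was not tested beyond these values and cannot be told apart from exchanged labels here.

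The second pattern was the fall of T lineage genes and the rise of myeloid genes with TAL1. Myeloid cells mixed into unchanged T lineage cells would lower T lineage genes by a common factor only if they expressed none of them. The 16 genes used, taken as absent from myeloid cells, had log2 fold changes with an SD of 1.96, from -7.76 for Dntt to -0.33 for Zap70. The largest standard error was 0.22 for Cd3d. Their median of -3.38 would need 90.4% of myeloid cells, and the larger fall of Dntt more. Low expression of some of these genes in the added cells would spread the falls too, and was not tested. The SD thus cannot decide between a mixture and a change of the cells' own expression with TAL1. The outgrowth of a rare cell type stays open as well and was not tested.

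The third pattern was a spread within groups that followed the share of reads outside genes. The sign of principal component 1 of this spread is arbitrary. It was set to make its correlation with that share negative. Over 24 stimulated libraries, within-group deviations of that share correlated with principal component 1 (41.0% of the within-group variance) at Pearson r of -0.99 and Spearman rho of -0.98, each with permutation p = 1e-05, the smallest 100000 permutations can give, or 2e-05 adjusted over 4 relations, and r was -0.99 without the 2 farthest libraries. Sequencing depth is argued against (r of 0.14, permutation p = 0.50, 0.60 adjusted; rho 0.11, permutation p = 0.60, 0.60 adjusted; r 0.19 without the 2 farthest libraries), and so is genomic DNA, since 1108 olfactory receptor genes held 4.53 of every 100 reads it would give them (11949 against 264002). Nuclear or unspliced RNA is a candidate explanation: the median slope of 4 nuclear RNAs was 0.0752 log2 per percentage point (Xist 0.0786, Malat1 0.0719, Neat1 0.0490, Kcnq1ot1 0.0897), against a range over all genes from -0.0682 to 0.0592 between the 5th and 95th percentile. In the transduced libraries the share fell with group, from 25.3 ± 0.017% with GFP to 21.3 ± 2.15, 17.8 ± 0.905 and 14.5 ± 0.912% with Pten gRNA, TAL1, and TAL1 and SCF, so there it is confounded with the groups. The stimulated groups differed in it as well: it was 44.9 ± 1.72% unstimulated, with group means from 34.0 to 39.6% in the 7 stimulations, and only DL4 libraries overlapped the unstimulated ones. The comparisons with unstimulated cells are thus confounded with it in part.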

How the results depend on the processing

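Tests with the no-feature share as a covariate and with exchanged or replaced SCF and IL7 labels were chosen only after the result was seen. DESeq2 size factors, no filter, the stricter filter and the DESeq2 Wald test left all 16 counts within 1.5 times their reported values.

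With the no-feature share as a covariate, 5 counts moved: IL7 3611, DL4 with SCF 3736, SCF with IL7 3765, Pten gRNA, TAL1 and SCF against GFP 7863, and the SCF difference 3965. The share nearly follows the transduced groups and was also higher unstimulated (44.9%) than in the stimulated groups (means 34.0 to 39.6%), and the cause was not tested. Fitting only the compared groups gave 2597 for IL7, 1393 for DL4 with IL7 and 1146 for SCF with IL7, where fewer libraries estimate the spread. Exchanging the SCF and IL7 labels took DL4 with IL7 to 476 (325 positive, 151 negative) and DL4 with SCF to 3128.

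Leaving out 1 library gave 739 to 1915 genes for DL4, 2251 to 3713 for SCF, 4027 to 7259 for IL7, 5810 to 6259 for DL4 plus SCF, 5230 to 6646 for DL4 plus IL7, 7115 to 7752 for SCF plus IL7 and 8372 to 8793 for the 3 stimuli. Interactions ranged over 1626 to 2573 (DL4 with SCF), 1843 to 4573 (DL4 with IL7) and 1539 to 3469 (SCF with IL7). Transduced comparisons ranged over 9498 to 10614, 12426 to 12491, 12653 to 12758, 11384 to 11841 and 5871 to 6441, and the SCF difference over 1538 to 3021. Shifts beyond 1.5 times came for DL4 without DL4 replicate 2 (859) or 3 (739) or unstimulated replicate 1 (902) or 2 (784), for SCF without SCF replicate 3 (2251) or unstimulated replicate 2 (2276), and without IL7 replicate 3 for DL4 with IL7 (4573) and SCF with IL7 (3469).

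The replicate number as a block changed no count by 1.5 times: it gave 1230, 3348, 5816, 6640, 6421, 7951 and 8917 for the stimulations, 2088, 2437 and 1888 for the interactions, and 10285, 12701, 12962, 11865 and 7247 for the transduced comparisons. After removing group means, libraries of a number had a mean r of -0.0029 over 84 stimulated and 0.031 over 18 transduced pairs (0.0011 and -0.016 for other numbers), with r over 0.1 in 27 and 2 pairs. A library of its own number was closest for 7 of 24 and 8 of 12 libraries, a hint of pairing in the latter, from the data and not the design.

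Camera called 162 of 336 list tests. An estimated correlation gave 67, all among the 162, and for fry, which tests other hypotheses, 238 were directional and 321 mixed. With the block, 150 of 315 were called, and with DESeq2 size factors 161.

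Same-direction overlaps of 1967, 1759, 1820 and 3199 genes were 377, 9, 94 and 186 at an absolute log2 fold change of at least 1, where fewer genes qualify, and 1, 2, 119 and 84 genes went opposite ways. With IL7-labelled libraries the second was 2887 and the first 1908, and with IL7 added to DL4 plus SCF the first was 2483.

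Of 5866 alternatives for 414 gene results, 56 crossed the threshold and 10 reversed. With the no-feature share as a covariate these were Tal1 in SCF plus IL7 (-0.0094) and in Pten gRNA, TAL1 and SCF against GFP (-0.89), and Unc5b with SCF (0.90), cause not tested. With labels exchanged they were, for DL4 with SCF, Timp3 (0.63), Vat1l (0.14) and Cish (0.25), for DL4 with IL7, Spred2 (0.52) and Cish (-0.15), and in the SCF difference, Etv5 (-2.60) and Cma1 (-0.037). Depth limits genes with few reads, which were not tested.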

Other observations

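The genes and tests of this part were chosen only after the result was seen.

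Several further genes moved with the groups, and Igf2 and H19, named above in other comparisons, are given over all 8 stimulated groups. Igf2, the imprinted growth factor gene, averaged 155 ± 21.6 CPM unstimulated, 173 ± 42.0 with DL4, 390 ± 114 in the libraries labelled SCF, 112 ± 31.0 in those labelled IL7, 746 ± 51.1 with DL4 plus IL7, 87.2 ± 11.9 with DL4 plus SCF, 444 ± 10.3 with SCF plus IL7 and 411 ± 33.4 with the 3 stimuli. H19, the neighbouring imprinted RNA gene, averaged 0.965 ± 0.197, 0.879 ± 0.176, 14.6 ± 1.94, 0.496 ± 0.0509, 19.6 ± 3.45, 2.22 ± 1.03, 13.4 ± 1.497 and 12.8 ± 0.792 CPM in the same groups. Igf2, H19 and Cish were highest in the same 4 of the 8 groups, with the SCF label, DL4 plus IL7, SCF plus IL7 and the 3 stimuli, and no correlation is given because the groups form separate clusters.

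In the transduced cells, the T cell receptor genes Trbv13-2 and Tcrg-C2 averaged 92.9 ± 6.65 and 744 ± 12.6 CPM with GFP, 88.8 ± 5.54 and 798 ± 28.0 with Pten gRNA, and 1.75 ± 0.112 and 33.4 ± 3.60 with TAL1. Cd34, a progenitor surface gene, averaged 115 ± 1.75, 163 ± 10.3 and 443 ± 23.7 CPM in these groups, Csf2rb, a myeloid cytokine receptor gene, 103 ± 2.30, 53.9 ± 1.16 and 684 ± 96.7, and the cell cycle inhibitor gene Cdkn2a 21.9 ± 1.08, 8.65 ± 0.879 and 4.04 ± 0.225 CPM.

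Y-linked genes were lower with TAL1 than with Pten gRNA: Kdm5d went from 167 ± 10.6 to 93.1 ± 2.71 CPM, Eif2s3y from 258 ± 20.4 to 157 ± 1.87, Uty from 79.3 ± 2.24 to 45.4 ± 1.05 and Ddx3y from 222 ± 8.52 to 153 ± 2.50. Their log2 fold changes had a median of -0.76, against -0.09 to 0.09 for the medians of the autosomes and -0.04 for X. Loss of the Y chromosome in part of the cells is a candidate explanation, since the 4 genes fell by much the same factor (SD 0.137). A common factor does not single out this cause. Other causes of it, and a change in the regulation of these genes, were not tested.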
